A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

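Messenger RNA was measured in budding yeast (Saccharomyces cerevisiae) passing through S phase, on Agilent yeast expression arrays with 8 arrays to a slide. Per the labels, cells of a MATa strain without BAR1 were held in G1 with alpha-factor at 0.25 µg per ml for 3.75 h at 30 °C and released with pronase at 20 µg per ml. They were collected after 32 min, called mid S, or 40 min, called late S. The release was done with or without 10 µM EdU, a thymidine analogue that is built into new DNA. The strain carries a viral thymidine kinase and a human nucleoside transporter, which let yeast take up and use the analogue. Per the labels, cDNA was made from about 30 µg of total RNA with an oligo-dT primer and hybridised against 2 µg of genomic DNA from G1 cells in the other dye, so the genomic DNA is a common reference and no sample of a group.

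There were 4 groups (mid or late S, without or with EdU) with 2 samples each. Each sample was hybridised on 2 arrays with opposite dyes, which gave 16 arrays and 8 samples. Per the file headers, the replicate number was also the slide, each of the 2 slides held all 4 groups, and the slides were scanned on different days. The labels conflict on time. For the 8 arrays without EdU the titles give the opposite minutes to the descriptions, source names and growth phase. For 4 arrays of slide 2 with cDNA in Cy5 the image names in the file headers give the other time. The description was followed throughout. Both exchanges were run as alternatives. With the image names' times each slide 2 sample averages an array described as mid S with an array described as late S. The phase differences of the dyes are then set against each other on that slide. Nothing in the labels says that the replicates came from separate cultures, so every p-value measures only the spread between these samples, which may be technical.

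The scanner files hold each spot's mean intensity and local background intensity in the Cy5 and Cy3 channels on a linear scale, per the file headers, with no normalization by the scanner software (Mapix 7.3.2). They also hold, per the file headers, the percent of a spot's pixels that lie above background plus 2 standard deviations and the percent that are saturated, in each channel. A table of processed log2 ratios was deposited for the same arrays, and the steps behind it are not given in the sources used here. In that table, 15 of 16 columns matched the scanner file of the same sample's opposite-dye array best, with the sign turned (r from -0.977 to -0.999 across spots), while the r with the column's own file was 0.816 to 0.969. The exception was the late S sample without EdU of slide 2 with cDNA in Cy5, at r = -0.958 with that file. The column medians lay between -0.08 and 0.18, so the ratios look nearly centred. Their exact centring and within-array steps stay unknown, and the table served only as an alternative (4297 genes).

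Each array held 15744 spots, of which 12512 were gene spots and 3232 were control or empty spots. The 6256 gene probes, each spotted 2 times, stood for 6225 genes or open reading frames, and 546 of these are described as dubious. Names were updated by systematic name through the reference gene table of assembly R64, which held 5720 of the 6225; other names are those of the array. Background was corrected with normexp (offset 50) on mean and local background signals. The log2 ratio of cDNA to genomic DNA was then formed with its sign set by the dye of the cDNA. No loess was applied within arrays, since cDNA against genomic DNA varies with abundance and a loess would remove that. The 16 columns were quantile normalized. Loess within arrays was still run as an alternative. Calls lost and medians shrunk under it are thus at least partly built in and do not measure stability. Control spots were left out after normexp. A spot counts as above background in a channel when at least 50% of its pixels exceed background plus 2 standard deviations. A probe counts as saturated on an array when at least 50% of its spots hold any saturated pixel, so its signal need not be clipped. Spots of a probe were averaged and then probes of a gene; for the 29 genes with several probes these differed by at most 0.41 in late minus mid S. Probes were kept where genomic DNA was above background on at least 8 of 16 arrays and cDNA on at least 4 of 16, which kept 6233 probes and 6202 genes. Of 23638 flagged gene spots over all arrays, 19883 were dim and 3526 were saturated at 50% of pixels or more, and these were kept. The 229 that were neither or had not been found were left out. Keeping the dim and saturated spots was decided after seeing the files.

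The 2 arrays of a sample were averaged before any test. limma (3.58.1, in R 4.3.3) was fitted per gene with a mean for each group over all 8 samples, followed by eBayes and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. All tests were two-sided. The groups, the use of the description over the titles, this fit without a term for the slide, the gene lists and the rule for named genes were all chosen before the data were examined. The slide as a block was the fit's alternative. The numbers do pair the samples. Deviations from the group means correlated at 0.80 to 0.90 across genes between samples of one slide, samples of one slide correlated at 0.97 to 0.99 against 0.89 to 0.92 between slides, and principal component 1, with 73.7% of the variance, separated the slides. The counts with the block had been seen by the time this check was made. Because the block changes most calls, the report gives both fits and uses the block for its verbs: "rose" and "fell" are said of genes called with it. The median standard error of a difference between groups was 0.325 without the block and 0.169 with it, and the number of arrays limits the precision of every value.

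Gene groups were 30 lists written from textbook yeast biology; their results stand in the report and in the closing part. Each was tested with camera at a preset correlation of 0.01, adjusted over the 30 lists of a comparison, with a correlation estimated per list and with fry as alternatives. Named genes followed a fixed rule. For each comparison it takes the 10 genes that rose most and the 10 that fell most among those called and changed the same way on both slides. Where fewer were called, the smallest p fill up to 5 per direction, given as values. For each list called by camera it takes the 3 members with the smallest p. It also always takes BAR1, URA3, CLN2, CLB6, RNR1, HTA1, HHF1, CLB2, SWI5, CDC20, SIC1, FUS1, MFA1, RNR3, HUG1, CDC21, ACT1 and TDH3. Applying the rule to the fit with the block as well was decided after seeing the data.

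The alternatives fixed in advance were the slide as a block, eBayes with trend and robust settings, a fit of all 16 arrays with a dye term, other normalizations (median centring, cyclic loess, loess within arrays), the scanner software's own background subtraction, no background subtraction, looser and stricter filters, arrays of 1 dye only, the deposited ratios, the titles' times, and each sample left out. Added after seeing the data were the image names' times, the fit without those 4 arrays, the block together with each other alternative, the estimated correlation and fry with the block, and the correlations under exchanged times. Leaving out a sample left its group with 1 sample. The spread then came from the other groups alone, so counts from those fits do not measure stability. The procedure was tested on simulated data for the real 6202 genes, with 100 genes changed by 1 and 100 by 2 on the log2 scale. In late minus mid S averaged over EdU, the fit with the block called 100% of either size and 12 unchanged genes. The fit without it called 30% and 82%, and 0 unchanged genes. For EdU minus none averaged over phase the shares were 100% and 100% with the block (19 unchanged genes called) and 22% and 72% without. Unchanged genes called with the block were most in late minus mid S with EdU, at 23, beside shares of 98% and 100%. A simulated list raised as a whole was called, and 0 of 20 unchanged lists were. Noise was drawn for each gene apart, with the spread of the fit with the block and the real difference between slides. The shares called with the block were thus largely built in. Simulated genes were not correlated, so the list result cannot show how camera copes with real correlation. Lists defined by position near centromeres or chromosome ends were not run, because no genome build was given for the array. The R64 table served only for names. Other tools were R's data.table package (version 1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.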

Results

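The 16 arrays gave mRNA levels, as log2 ratios of cDNA to G1 genomic DNA, in 8 samples: 2 of mid S and 2 of late S cells without EdU, and 2 of each with EdU. The series is about how nucleosome positions mature after replication, and the arrays show which transcripts were present at the times and in the EdU treatment used to sample S phase. cDNA was above background for 5562 to 6035 of 6256 probes on the arrays of slide 1 and for 5966 to 6238 on those of slide 2. Slide 2 was brighter, with 78 to 490 probes holding any saturated pixels in cDNA per array against 0 to 19 on slide 1. The number of arrays limits the precision: each group had 2 samples, 1 on each slide.

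BAR1, the protease gene deleted in this strain, was above background in genomic DNA on 0 of 16 arrays, at -5.16 ± 1.38 (SD) log2 units from the array median, a level set by the floor of the correction (-3.87 on slide 1 and -6.44 on slide 2). Its cDNA was above background on 0 of 16 arrays as well, at -4.23 ± 0.74. URA3, the selectable marker used to insert the thymidine kinase, was above background in both channels on 16 of 16 arrays. Its genomic DNA signal lay 2.11 ± 0.60 above the array median, between percentiles 96.5 and 99.5 of all probes.

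Late minus mid S without EdU asks what changed between 32 and 40 min after release in untreated cells. With the slide as a block, 18 of 28 genes of the CLB2 cluster, which are transcribed in G2/M, rose and 26 of 53 G1/S transcripts fell. HOF1 (YMR032W), which encodes a protein of the cytokinetic ring, rose most, by 2.67 on the log2 scale (SE 0.22 with the slide as a block and 0.46 without). RNR1 (YER070W), the large subunit of ribonucleotide reductase, fell by 1.98 (SE 0.22 and 0.29). HOF1 cDNA was above background on only some arrays of a group. RNR1, and MRH1 named below, had saturated pixels on some. The sizes of these differences may thus depend on the background correction or on saturation. limma with the slide as a block called 89 of 6202 genes, 40 higher and 49 lower in late S, and all 89 had the same sign on both slides. The spread in this fit is the disagreement between the slides, so the shared sign of called genes is largely built in. Over all genes, called or not, the difference on slide 1 against that on slide 2 gave r = 0.34. Leaving out 1 sample at a time gave between 25 and 97 calls, and the 97, without the late S sample of slide 2, shared 45 with the 89. Without the block it called 0, with 151 genes at an unadjusted p under 0.05 against 762 with the block, and the 16-array fit with a dye term called 4.

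Among the genes that rose without EdU, MRH1, a plasma membrane protein gene, rose by 2.31 (adjusted p = 0.001316 with the block, 0.2515 without; 2.64 on slide 1 and 1.98 on slide 2). CHS2, the chitin synthase of the primary septum, rose by 1.92 (1.95 and 1.89 on the slides; adjusted p = 0.003421 with the block, 0.4275 without). HST3, a deacetylase of histone H3, rose by 1.57, CDC20, an activator of the anaphase-promoting complex, by 1.53, and SWI5, a transcription factor of the M/G1 boundary, by 1.65. MMR1, needed for mitochondrial inheritance, rose by 1.78, WSC4 by 1.73, the eisosome gene NCE102 by 1.54 and IRC8 by 1.47. In the average over EdU, given below, NCE102 changed sign after loess within arrays. The mitotic cyclin gene CLB2 itself rose by 0.95 (adjusted p = 0.02837 with the block).

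RNR1 was among the 10 genes that fell most without EdU, and the others follow. YBR071W, an open reading frame of unknown function, fell by 1.98 (adjusted p = 0.001316 with the block, 0.2792 without). The cohesin gene MCD1 fell by 1.58 and the cohesin maintenance gene PDS5 by 1.51. POL30, which encodes the replication clamp PCNA, fell by 1.47, the mismatch repair gene MSH6 by 1.45 and the transcription factor gene TOS4 by 1.45. ERP3 (-1.53), the cell wall gene SVS1 (-1.50) and CSI2 (-1.46) complete the 10. The G1 cyclin gene CLN2 fell by 1.19 (adjusted p = 0.005881 with the block; -1.12 on slide 1 and -1.26 on slide 2).

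**Figure D1:**
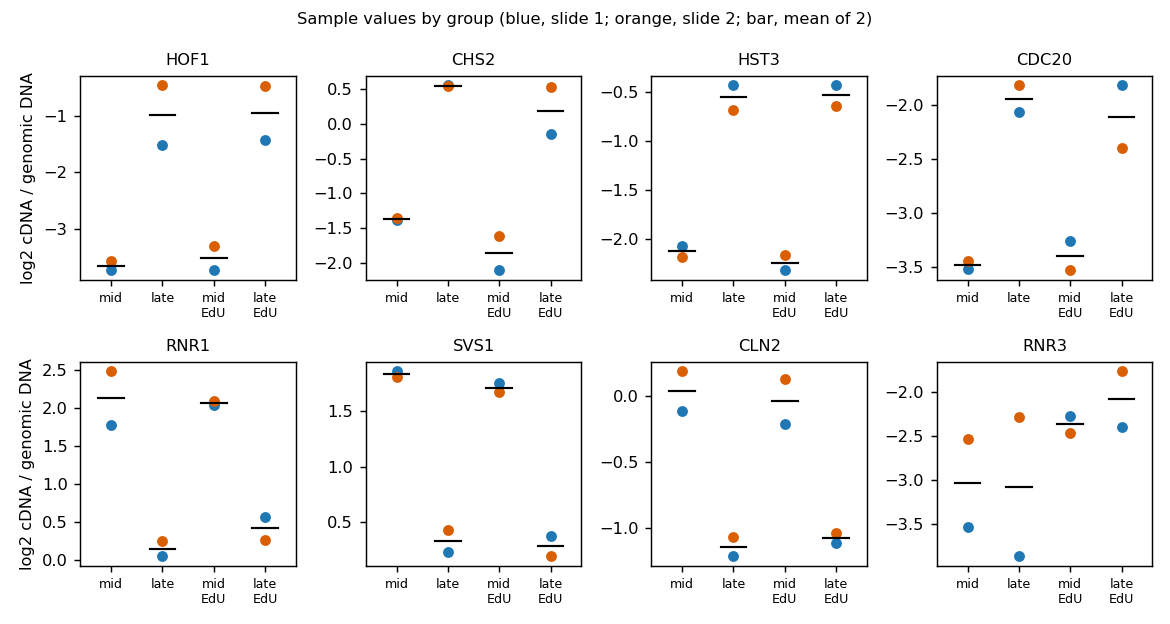
Log2 ratio of cDNA to genomic DNA for 8 genes in each of the 8 samples, by group, with samples of slide 1 in blue and of slide 2 in orange; the bar is the mean of the 2 samples. HOF1, CHS2, HST3 and CDC20 lie higher and RNR1, SVS1 and CLN2 lower in late than in mid S on both slides, with and without EdU, while RNR3 was called in no comparison.

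Of the 30 lists, camera called 10 with the block and 9 without, or 1 and 2 with an estimated correlation; groups that were also called in the average are described there. The CLB2 cluster of G2/M genes had a median of 0.95 without EdU (0.94 on slide 1, 1.02 on slide 2). Of its 28 members, 18 rose with the block and 0 fell, or 22 when adjusted over the list alone. Its camera adjusted p was 2.93e-29 with the block, and it held at adjusted p = 0.04527 with an estimated correlation. The G1/S transcripts, targets of the MBF and SBF factors, had a median of -0.83, with 26 of 53 members falling and 0 rising (42 adjusted over the list alone). Their camera adjusted p was 5.33e-46 with the block, and adjusted p = 0.1451 with an estimated correlation; without the block these were 1.22e-55 and 0.019. No single member of either list passed without the block over all genes (15 CLB2 cluster and 25 G1/S members when adjusted over the list alone). Called with the block only were the mitochondrially encoded genes, at a median of -0.53 with 7 of 7 below 0 (-0.59 on slide 1 and -0.23 on slide 2; adjusted p = 0.007115 with the block, 0.06994 without, and 0.3703 with an estimated correlation), and the core histones, at -0.28 (-0.63 on slide 1 and 0.08 on slide 2; 0.0235 with the block, 0.1257 without, and 0.5987 with an estimated correlation). In both lists 0 members were called over all genes, and 1 mitochondrial and 0 histone members when adjusted over the list alone. With the titles' times for these samples, every direction without EdU turns around; the 89 calls would then be 49 higher and 40 lower. The count was 0 after loess within arrays, with the scanner software's background subtraction, from arrays with cDNA in Cy3 alone and with the image names' times.

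Late minus mid S with EdU asks the same of cells released into the analogue, where titles and descriptions give the same times. With the block, 16 of 28 CLB2 cluster genes rose and 25 of 53 G1/S transcripts fell. HOF1 rose by 2.58 (SE 0.22 with the block, 0.46 without; limma adjusted p = 0.002313 and 0.5629) and CHS2 by 2.05. PCL1, a cyclin gene of the Pho85 kinase active in G1, fell most, by 1.85 (SE 0.16 and 0.26; adjusted p = 0.002313 with the block; -2.06 on slide 1 and -1.63 on slide 2). With the block 70 genes were called, 32 higher and 38 lower, all 70 with the same sign on both slides and 538 at an unadjusted p under 0.05. The shared sign is again largely built in, and r between slides over all genes was 0.47. limma without the block called 0 (118 at an unadjusted p under 0.05), and the 16-array fit called 2.

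MRH1 (1.85), HST3 (1.70), WSC4 (1.72), MMR1 (1.68), IRC8 (1.58) and NCE102 (1.41) rose with EdU as they had without it. SFG1, a transcription factor gene, rose by 1.37 and the kinase gene ALK1 by 1.34. Falling genes again included RNR1 (-1.64), MCD1 (-1.77), YBR071W (-1.76), POL30 (-1.56), PDS5 (-1.44), SVS1 (-1.43) and MSH6 (-1.42). POL1, the catalytic subunit of DNA polymerase alpha, fell by 1.64 and the cell wall gene TOS6 by 1.58. All of these were called with the block. SWI5 was at 1.14 (adjusted p = 0.129) and was not called with EdU.

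Camera called 10 of 30 lists with EdU with the block and 8 without, or 1 and 2 with an estimated correlation. The CLB2 cluster had a median of 1.00 and the G1/S transcripts one of -0.87. Adjusted over the list alone, 23 CLB2 cluster members rose and 39 G1/S members fell. The camera adjusted p with the block was 3.41e-34 for the CLB2 cluster, with adjusted p = 0.03575 with an estimated correlation. For G1/S it was 1.39e-53, with adjusted p = 0.1164 with an estimated correlation. Called with the block only were glycolysis genes, at a median of -0.23 (adjusted p = 0.02421 with the block, 0.08456 without, and 0.6214 with an estimated correlation), and purine biosynthesis genes, at 0.10 (0.02506, 0.05512 and 0.4278), each with 0 members called over all genes and 0 adjusted over the list alone. The count of 70 fell to 0 under the same 4 settings as without EdU, and leaving out 1 sample at a time gave between 1 and 78 calls.

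Set against each other, the phase differences with and without EdU came from separate samples. Of the genes higher in late S, 26 were shared between the 40 and the 32 called with the block (0.21 by chance for independent lists). Of those lower, 34 were shared between 49 and 38 (0.30 by chance). The calls share each gene's spread estimate, so the lists are not independent and these chance counts are only a rough guide. Across all 6202 genes the differences correlated with Pearson r = 0.63 and Spearman rho = 0.49, and 66.3% had the same sign. Within slides r was 0.44 and 0.48, and between slides 0.39 and 0.47. Over the 145 genes of the fixed cell cycle lists r was 0.96. These are correlations across genes, which are not independent replicates. With the titles' times r becomes -0.63.

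**Figure D2:**
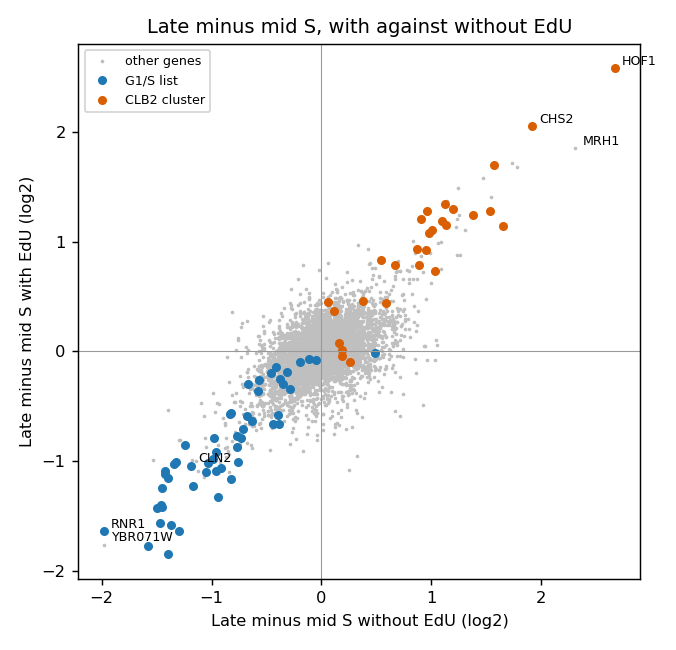
Late minus mid S with EdU (y axis, log2) against late minus mid S without EdU (x axis, log2), 1 point per gene, with G1/S transcripts in blue and the CLB2 cluster in orange. HOF1, CHS2 and MRH1 lie at the upper right and CLN2, RNR1 and YBR071W at the lower left; across genes r = 0.63.

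Averaging over EdU set 4 late against 4 mid S samples. HOF1 (2.63, SE 0.16), MRH1 (2.08, SE 0.13), CHS2 (1.99, SE 0.14) and HST3 (1.64, SE 0.11) rose most clearly, and YBR071W (-1.87, SE 0.11), RNR1 (-1.81, SE 0.16), MCD1 (-1.68) and PCL1 (-1.62) fell. limma with the block called 209 genes, 78 higher and 131 lower, with a median size of 0.76 and the same sign on both slides for all 209. Here too the shared sign is largely built in, and r between slides over all genes was 0.56. Without the block it called 4 (239 at an unadjusted p under 0.05, against 1036 with the block): MRH1 (adjusted p = 0.04711), HST3 (0.04737), YBR071W (0.04711) and SVS1 (0.04987). The 16-array fit called 51. With the block the count was 1 after loess within arrays, 82 with the scanner software's background subtraction, 42 from arrays with cDNA in Cy3 alone, and 0 with the titles' or the image names' times. Leaving out 1 sample at a time gave between 103 and 217.

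Of the G1/S transcripts, 39 of 53 fell in the average and 0 rose (47 adjusted over the list alone), around a median of -0.89. Besides RNR1 and MCD1 these included POL30 (-1.52), POL1 (-1.47), TOS6 (-1.47), MSH6 (-1.43), CLN2 (-1.11), the thymidylate synthase gene CDC21 (-1.03) and the histone chaperone gene ASF1 (-1.28). CLB6, an S phase cyclin gene on the same list, was at -0.25 and was not called. The list had a camera adjusted p of 1.55e-50 with the block and an adjusted p = 0.1267 with an estimated correlation; without the block these were 1.56e-62 and 0.01511. When loess was applied within arrays, the list's median was -0.27, still called (adjusted p = 1.16e-11), and POL30 changed sign to 0.06.

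Of the CLB2 cluster, 21 of 28 members rose and 0 fell (22 adjusted over the list alone), around a median of 0.98, and 28 of 28 lay above 0. CDC20 rose by 1.41, SWI5 by 1.40 and CLB2 by 0.94. Camera gave an adjusted p of 1.78e-31 with the block and it held at adjusted p = 0.04053 with an estimated correlation; after loess within arrays the median was 0.36 (adjusted p = 1.03e-11). In each of the 8 pairs of a late and a mid S array of the same slide, dye and treatment, the CLB2 cluster's median lay between 0.79 and 1.05 and that of the G1/S transcripts between -1.02 and -0.74.

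**Figure D3:**
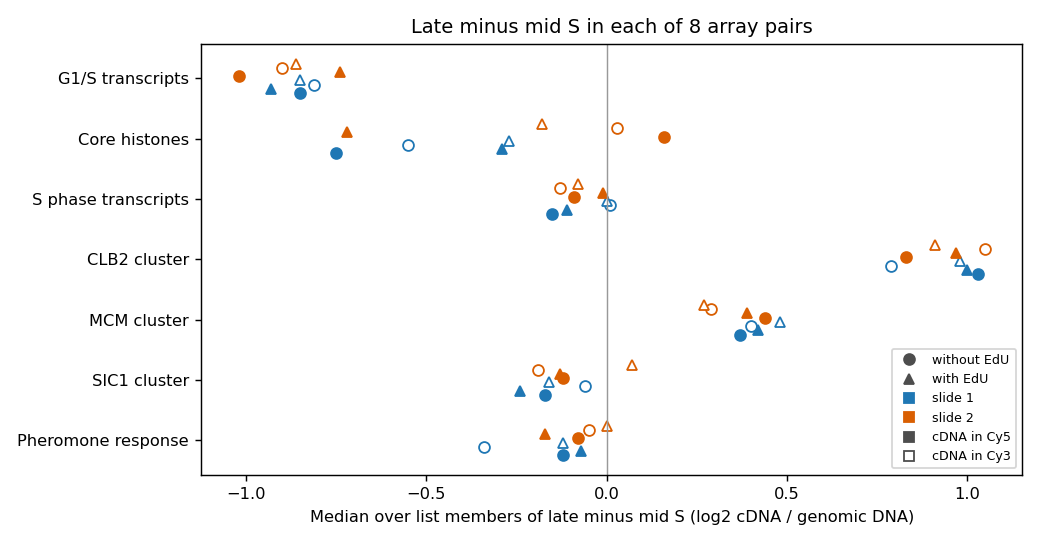
Median late minus mid S difference (log2) of 7 cell cycle and pheromone lists in each of the 8 array pairs; blue is slide 1 and orange slide 2, filled symbols have cDNA in Cy5 and open ones in Cy3, circles are without and triangles with EdU. The G1/S transcripts lie between -1.02 and -0.74 and the CLB2 cluster between 0.79 and 1.05, while the core histones range from -0.75 to 0.16.

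Of the MCM cluster, genes that peak at M/G1 and license replication origins, 3 of 9 rose and 1 fell (6 and 1 adjusted over the list alone), with a median of 0.45. The helicase genes MCM7 (1.18) and MCM3 (0.72) and the loader gene CDC6 (0.50) rose, while SWI4, a subunit of SBF, fell by 0.76. The list's camera adjusted p was 5.47e-04 with the block, and adjusted p = 0.4377 with an estimated correlation. Its call was also lost after loess within arrays (0.04, 0.685) and with the image names' times (0.19, 0.06327). With the titles' times 0 of the 12 lists tried again in the average were called. Core histone genes had a median of -0.38 (-0.51 on slide 1 and -0.16 on slide 2), with 2 of 8 falling (3 adjusted over the list alone): HTB2 (-0.62) and HHT1 (-0.61), both saturated on up to 2 of 4 arrays of a group. HTA1 was at -0.35 and HHF1 at -0.42, saturated on up to 2 and 3 of 4 arrays of a group, and the list had camera adjusted p = 0.001733 with the block and adjusted p = 0.4377 with an estimated correlation. Its call was also lost from arrays with cDNA in Cy3 (-0.31, 0.1307), after loess within arrays (-0.28, 0.374), with the image names' times (-0.19, 0.08917), without those 4 arrays (-0.31, 0.05539) and without the mid S sample without EdU of slide 1 (-0.18, 0.1256). Nucleosome assembly and remodelling genes had 6 of 49 members falling and 0 rising (10 adjusted over the list alone), among them ASF1, which is also on the G1/S list, the CAF-1 subunit gene CAC2 (-0.92) and HIF1 (-0.77). Their median was -0.04, with camera adjusted p = 0.03796 without the block, 0.07309 with it and 0.4016 with an estimated correlation.

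Each of the remaining lists that camera called in the average lost its call with an estimated correlation. The other alternative, fry, called 5 lists in the average with the block. These were the CLB2 cluster (adjusted p = 3.42e-04), G1/S transcripts (0.005066), mitochondrial ribosomal proteins (0.03784), the SIC1 cluster (0.03784) and the iron regulon (0.04647). Without the block fry called 3, the CLB2, G1/S and SIC1 lists. The iron regulon had a median of 0.18 (0.31 without the mid S sample with EdU of slide 1), and 5 of 17 members rose (7 adjusted over the list alone), among them the siderophore transporter gene SIT1 (1.03), the reductase gene FRE1 (1.07) and the oxidase gene FET3 (0.80); camera adjusted p = 7.27e-05 with the block and adjusted p = 0.4147 with an estimated correlation (0.374 after loess within arrays, at 0.11). Mitochondrial ribosomal proteins had a median of 0.25, with 54 of 56 above 0 but 0 called over all genes (12 adjusted over the list alone); camera adjusted p = 9.55e-12 with the block and adjusted p = 0.3255 with an estimated correlation (0.374 after loess within arrays, at 0.04). Drug resistance and efflux genes had a median of 0.14, and 2 of 18 rose, the polyamine exporter genes TPO3 (1.25) and TPO1 (0.68), also 2 when adjusted over the list alone; camera adjusted p = 0.005226 with the block and adjusted p = 0.4377 with an estimated correlation. That call was also lost after loess within arrays (0.04, 0.4214), with the image names' times (0.06, 0.476) and without the late S sample with EdU of slide 2 (0.07, 0.09336). Stress-induced genes had a median of -0.18, with 3 of 40 falling (12 adjusted over the list alone). HXK1 (-0.56), TSL1 (-0.56) and HSP26 (-0.52) fell, and YGP1 rose by 1.36. The list had camera adjusted p = 4.26e-04 with the block and adjusted p = 0.4377 with an estimated correlation. Its median was -0.10 after loess within arrays. It was -0.12 with the image names' times and also without the mid S sample without EdU of slide 2.

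Ribosome biogenesis genes had a median of 0.10, which turned to -0.04 under loess within arrays (adjusted p = 0.374) and was 0.04 with the image names' times (0.08917), and the RNA helicase gene DBP2 (0.55) was the 1 of 62 that rose (0 adjusted over the list alone; camera adjusted p = 0.002556 with the block and adjusted p = 0.4377 with an estimated correlation). Purine biosynthesis genes, called with the block only, had a median of 0.13, with 1 of 21 rising, GCV2 at 0.62 (2 adjusted over the list alone; camera adjusted p = 0.03031 and adjusted p = 0.4164 with an estimated correlation). The pheromone response list had a median of -0.11, with 1 of 27 falling (3 adjusted over the list alone), the agglutinin gene AGA2 (-0.78); FUS1 and the a-factor gene MFA1, which was counted among the a-specific genes, were not called. Its camera adjusted p was 0.01981 with the block and adjusted p = 0.5226 with an estimated correlation. The call was also lost from arrays with cDNA in Cy3 (0.1307), after loess within arrays (0.06838), with the image names' times (0.1661), without those 4 arrays (0.0885) and without any of 3 samples of slide 1 (0.1343, 0.1092 and 0.05613). The SIC1 cluster of M/G1 and daughter cell genes had a median of -0.09, with 1 of 18 falling (3 adjusted over the list alone), BUD9 (-0.79), while SIC1 itself was at -0.24; camera adjusted p = 0.02791 with the block and adjusted p = 0.4147 with an estimated correlation. The call was also lost from arrays with cDNA in Cy3 (0.1694), after loess within arrays (0.394), in the deposited ratios (0.0555), with the image names' times (0.1939), without those 4 arrays (0.08271) and without any of 3 single samples (0.05102, 0.07498 and 0.05198).

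EdU minus none asks whether the analogue changed transcript levels, in mid S, in late S and over both. No gene passed in any of the 3 comparisons: limma called 0 in mid S (7 genes at an unadjusted p under 0.05 without the block and 299 with it), 0 in late S (9 and 253) and 0 over both phases (23 and 425). Chance alone would put a share of about 0.05 of all genes under that p. The counts with the block in mid and in late S do not exceed that share, and the count over both phases does. Without the block the difference between slides is part of the spread, so its counts lie far below that share. The 16-array fit called 0 in each. The smallest adjusted p with the block was 0.9996, 0.6486 and 0.6908.

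None of the genes named next was called, and they are given as values only. In mid S the elongation factor gene EFT1 was 0.81 higher with EdU (SE 0.16 with the block; 0.59 on slide 1 and 1.03 on slide 2), the glycolytic gene TPI1 0.79 higher and the ribosomal protein gene RPS12 0.98 higher. YNK1, a nucleoside diphosphate kinase gene, was at -0.61 and SUI2, a translation initiation factor gene, at -0.58. In late S, PAU15 was at -0.90 (SE 0.15; -0.83 and -0.96 on the slides), YJL220W at -1.05 and YCR102W-A at -0.96, while UBC12 was at 0.74 and RPS1A at 0.73.

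Over both phases the cytosolic ribosomal proteins had a median of 0.16 (0.12 on slide 1, 0.25 on slide 2), and 104 of 137 lay above 0, with 0 called over all genes and 0 adjusted over the list alone. Camera called this list (adjusted p = 3.43e-08 with the block and 1.39e-07 without), but adjusted p = 0.898 with an estimated correlation and the block, and 0.9876 without the block. The median was 0.03 from arrays with cDNA in Cy5 (adjusted p = 0.5747), 0.30 from those with cDNA in Cy3 (3.13e-08) and 0.05 in the deposited ratios (0.7783), and it was 0.09 without the late S sample without EdU of slide 2 (0.06617). In mid S alone it was 0.14 (adjusted p = 2.69e-06 with the block, 0.8076 with an estimated correlation) and in late S 0.15 (1.33e-04 and 0.9685). RPS12 and RPS1A, 2 of its members, were saturated in cDNA on up to 3 and 2 arrays of 4 in a group. Glycolysis genes were called with the block only, at a median of 0.18 over both phases (adjusted p = 0.02375, and 0.898 with an estimated correlation) and 0.23 in mid S (0.001957 and 0.8076). Core histones (0.22) and mitochondrially encoded genes (-0.23) were called in mid S with the block (adjusted p = 0.04414 for each, and 0.9119 and 0.8076 with an estimated correlation); the histone median was -0.14 on slide 1 and 0.72 on slide 2.

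Genes of DNA damage and replication stress had a median EdU difference of 0.03 over both phases (camera adjusted p = 0.9354 without the block and 0.8094 with it). Genes of pyrimidine and deoxynucleotide metabolism had one of 0.01 (0.9801 and 0.8094). RNR3, a damage-induced subunit of ribonucleotide reductase, was at 0.83 (SE 0.24 with the block; 1.37 on slide 1 and 0.29 on slide 2) and the damage-induced inhibitor gene HUG1 at 0.47 (0.94 and -0.01), neither of them called. RNR1 was at 0.10, CDC21 at -0.04, CLB2 at 0.36 and URA3 at 0.08. G1/S transcripts (0.05) and the CLB2 cluster (0.02) were not called between EdU and none.

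EdU differences in mid and late S correlated across all genes with r = 0.32 and rho = 0.34, from separate samples, and 62.2% of genes had the same sign. Within slide 1 r was 0.43 and within slide 2 it was 0.02; between slides it was -0.01 and 0.04. Averaged over phase, the EdU difference of slide 1 against that of slide 2 gave r = -0.00, against 0.56 for the phase difference averaged over EdU. Genes are not independent replicates in any of these.

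**Figure D4:**
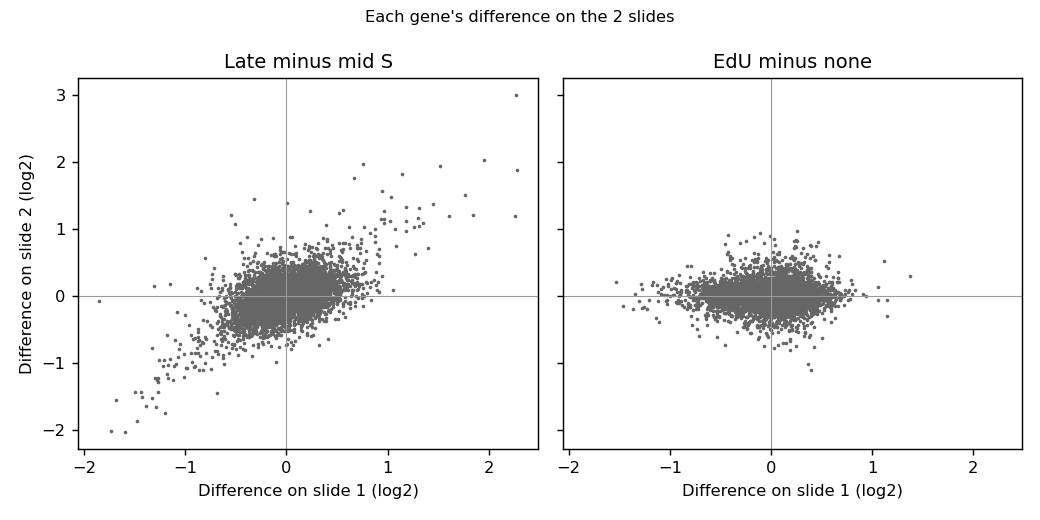
Differences on slide 2 (y axis, log2) against those on slide 1 (x axis, log2), 1 point per gene: late minus mid S averaged over EdU on the left (r = 0.56) and EdU minus none averaged over phase on the right (r = -0.00). The phase differences of the strongest genes lie along the diagonal, and the EdU differences do not.

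The interaction asks whether the phase difference depended on EdU. limma called 0 genes with the block (108 at an unadjusted p under 0.05, smallest adjusted p 0.9991) and 0 without it (5), and 0 in the 16-array fit. PAU15 was at -1.04 (SE 0.21), CWP2 at 0.75 and SRX1 at 0.70, as values. With the titles' times the fit without the block called 4, since that exchange makes the interaction the averaged phase contrast. The mitochondrially encoded genes had a median of 0.36 (0.71 on slide 1 and 0.29 on slide 2), with 7 of 7 above 0, 0 called over all genes and 0 adjusted over the list alone. VAR1 was at 0.85, COB at 0.88 and OLI1 at 0.76. Camera gave an adjusted p of 0.004703 with the block and 0.1567 without, and adjusted p = 0.9012 with an estimated correlation; with median centring it was 0.1199 at a median of 0.26.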

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

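Of the tests in this part, the repeats of the interaction under other settings with the block were chosen after the result was seen. A difference between the groups stood out in 1 list. The mitochondrially encoded genes had a median interaction of 0.36, meaning that late minus mid S was higher with EdU than without, with the slide as a block (camera adjusted p = 0.004703, but 0.9012 with an estimated correlation and 0.1567 without the block). All 7 measured members lay above 0: COX1 (0.36), COX2 (0.35), COX3 (0.18), COB (0.88), ATP8 (0.36), OLI1 (0.76) and VAR1 (0.85). In mid S the EdU difference ran from -0.65 for VAR1 to 0.11 for COB, and in late S from -0.28 for COX3 to 0.99 for COB. The cDNA was primed on poly(A), which most yeast mitochondrial messages lack, so these probes report on transcripts the method was not made to capture. By dye, the median was 0.34 from arrays with cDNA in Cy5, where the call was lost (adjusted p = 0.2488), and 0.70 from arrays with cDNA in Cy3 (0.0261). The call was also lost with median centring (0.26, 0.1199), cyclic loess (0.33, 0.06361), loess within arrays (0.17, 0.993) and the image names' times (0.32, 0.2106). It was kept at 0.67 with the software's background subtraction (0.04264), at 0.60 with the strict filter (0.02667), and without the mid S sample without EdU (0.54, 0.01071) or the late S sample with EdU (0.61, 0.009502) of slide 2. It was lost without the mid S sample without EdU of slide 1 (0.48, adjusted p = 0.05228), the late S sample without EdU of slide 1 (0.42, 0.1976) or the late S sample with EdU of slide 1 (0.54, 0.1412), and the median turned to -0.37 with the titles' times, as their exchange in the samples without EdU allows.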

How the results depend on the processing

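Settings combined with the slide as a block, the image names' times and the fit without those 4 arrays were chosen after the results were seen; the others were fixed in advance. With the block alone, late minus mid S went from 0 to 89 calls without EdU, from 0 to 70 with EdU and from 4 to 209 averaged. It changed no call of a gene in the EdU comparisons or the interaction, which stayed at 0. The slides take most of the variance, which the block removes. Without the block, the 16-array fit gave 4, 2 and 51, and the averaged count was 0 under loess within arrays, software background subtraction, Cy5 arrays alone, Cy3 arrays alone, the deposited ratios, the titles' times, the image names' times and without those 4 arrays; leaving out any 1 of the 8 samples gave 0 to 0. The interaction went from 0 to 4 with the titles' times, whose exchange turns it into the averaged phase contrast, where 4 are called. With the image names' times the slide 2 samples mix arrays described as mid and late S, which sets their phase differences against each other. Loess within arrays takes out signal that follows abundance, by construction. For the other counts the cause was not tested, beyond the smaller number of arrays where some were left out.

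With the block, the counts without EdU, with EdU and averaged were 186, 151 and 448 in the 16-array fit (where the arrays of a sample, at a consensus correlation of -0.08, count about as separate samples), 0, 0 and 1 after loess within arrays, 0, 0 and 82 with software background subtraction, and 0, 0 and 42 from Cy3 arrays alone. They were 0, 0 and 0 with the image names' times and 46, 30 and 131 without those 4 arrays, where all 46 and all 30 were among the 89 and 70. The averaged count was 0 with the titles' times, which set the opposed samples against each other. A 2-fold minimum left 52 of 89 and 58 of 209. In the fits with a sample left out, its group has 1 sample and the spread comes from the other groups. Leaving out 1 sample gave 25 to 97 without EdU: 25 without the mid S sample of slide 1 and 26 without the late S sample of slide 1, 38 without the mid S sample of slide 2, and 59 without the late S sample with EdU of slide 1 or of slide 2. With EdU the range was 1 to 78: 1 and 6 without the mid S samples of slides 1 and 2, and 14 and 10 without the late S samples. Averaged it was 103 to 217: 109 and 103 without the mid S samples with EdU of slides 1 and 2, and 131 and 104 without the late S ones. The deposited ratios split the calls without EdU into 31 higher and 70 lower, against 40 and 49. EdU minus none averaged over phase stayed at 0 with the block under every setting run, by limma (425 genes at an unadjusted p under 0.05 in the reported fit). The image names' times set the phase differences of the dyes on slide 2 against each other, by construction. Loess within arrays takes out signal that follows abundance, also by construction. For the other settings the cause was not tested except where samples or arrays were left out.

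Over the 7 comparisons of 30 lists camera called 32 without the block, against 6 with an estimated correlation and 8 with fry; with the block it called 40, against 3 and 9. The correlation of the phase differences, 0.63, was 0.59 with median centring, 0.96 over the cell cycle lists, 0.27 with the image names' times and -0.63 with the titles' times, as a change of sign must give. The correlation of the EdU differences of mid and late S was 0.32, and -0.01 and 0.04 when the 2 came from different slides; the EdU difference averaged over phase, a different quantity, gave -0.00 between replicates 1 and 2. BAR1 cDNA was -6.79 in the software's signals, from the 1 array with a positive value.

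Of the averaged phase results with the block, those that turned under the titles' times did so near 0, by the construction of that average: G1/S 0.02, MCM cluster -0.03, SIC1 cluster 0.02, pheromone response 0.03, iron regulon -0.02, stress 0.02, nucleosome assembly 0.02, drug efflux -0.05 and mitochondrial ribosomal proteins -0.01, and among genes HOF1 -0.05, MRH1 -0.23, MMR1 -0.05, WSC4 -0.01, SWI5 -0.25, NCE102 -0.06, CDC20 -0.13, RNR1 0.17, YBR071W 0.11, ERP3 0.27, PDS5 0.04, SVS1 0.03, CSI2 0.03, MSH6 0.02, TOS4 0.10, CLN2 0.08, CLB2 -0.01 and CDC21 0.01. The interaction of the mitochondrially encoded genes turned to -0.37. Under loess within arrays ribosome biogenesis turned to -0.04, NCE102 to -0.29 and POL30 to 0.06. That loess takes out signal that follows abundance, so a shrinkage towards 0 is built in. Why these changed sign was not tested. A called gene was counted as the same if it kept its direction and call. An uncalled gene was counted so if it stayed uncalled and moved by under its standard error. Of 39 single genes, 39 were the same without background subtraction, 38 with median centring and 37 with cyclic loess. From Cy5 arrays 37 were the same, from Cy3 arrays 31 and after loess within arrays 6. Of 12 lists, 3 kept direction and call after loess within arrays. Leaving out 1 sample ended list calls in the average: core histones without the mid S sample of slide 1 (-0.18), pheromone response without the late S sample (-0.13) or the EdU samples of slide 1 (-0.11 mid, -0.13 late), the SIC1 cluster without those EdU samples (-0.12 and -0.12) or the late S sample of slide 2 (-0.10), and drug efflux without the late S sample with EdU of slide 2 (0.07). Among other medians that moved by 1.5 times or more and kept their call were core histones -0.24 without the late S sample with EdU of slide 1; the iron regulon 0.27 and 0.31 without the late S sample without EdU or the mid S sample with EdU of slide 1, 0.44 with software background subtraction, 0.42 with the strict filter, 0.29 from Cy3 arrays and 0.37 in the deposited ratios (0.11 after loess within arrays, where its call was lost, adjusted p = 0.374); the SIC1 cluster -0.15 and -0.05 without the late S sample of slide 1 or the mid S sample of slide 2, both without EdU; and drug efflux 0.09 and 0.21 without the late S samples without EdU of slides 1 and 2. The cytosolic ribosomal proteins' EdU median of 0.16 was 0.27 with median centring, 0.32 with software background subtraction, 0.28 without the 4 arrays, 0.08 with cyclic loess and 0.09 after loess within arrays. No scaling moved the median of all genes by over 0.1. Scaling between arrays nearly fixes that median, so a shift of all genes would not show. Signal over background limits the low end: 23 probes were left out as dim, and HOF1 was above background in cDNA on as few as 2 of 4 arrays of a group, while at the bright end RNR1 and MRH1 were saturated on up to 2 of 4.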

Other observations

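The splits of the samples were fixed in advance; the tests of the times, the scan gain and the slides were chosen after the results were seen. Several groups tied to S phase, nucleotide supply and growth were not called in late minus mid S averaged over EdU. S phase genes of the Hcm1 regulator had a median of -0.04 (camera adjusted p = 0.2325 without the block and 0.3653 with it). With the block 2 of 29 rose and 2 fell. DNA damage genes had a median of -0.05 (0.3049 and 0.3644), and with the block 0 rose and 2 of 26 fell. Pyrimidine and deoxynucleotide genes were at 0.00 (0.5483 and 0.6589), with 1 of 26 rising and 3 falling with the block. Cytosolic ribosomal proteins were at -0.02 (0.6961 and 0.7242). Medians of metabolic groups were glycolysis -0.09 (called with EdU alone, with the block, at -0.23), respiratory chain and TCA cycle -0.01, ergosterol -0.05, Gcn4 targets of amino acid starvation 0.02, methionine and sulfur assimilation 0.09 and phosphate starvation 0.01, although 3 of the 15 phosphate genes rose with the block. Heat shock genes were at -0.05, quiescence genes at 0.01, meiosis genes at -0.04, a-specific genes at 0.02, the alpha-specific genes of the other mating type at 0.04, mitochondrially encoded genes at -0.19 (called without EdU, with the block, at -0.53) and strain markers at 0.09.

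Whether a probe without signal in genomic DNA marks sequence missing from the strain or does not hybridise was not tested. Of all gene probes, 10 were above background in genomic DNA on 0 of 16 arrays: those of BAR1, PDR18, YGL262W, AIF1, YAR047C, COS12, YBR012C, YBR013C, YNR071C and ATP6. Their levels lie at the floor and have no order. Among the strain's marker genes, TRP1 lay at 1.43, AUR1 at 1.36 and ADE2 at -0.98 log2 units from the array median in genomic DNA, levels that also depend on each probe.

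The pattern of falling G1/S and rising CLB2 cluster genes rests on times that the labels give in conflict. If the titles held for the samples without EdU, late minus mid S would run against itself between the EdU conditions, and r = 0.63 across genes argues against that. If the image names held for 4 arrays of slide 2, the CLB2 cluster would lie below the G1/S transcripts in their pairs, but it lay above by at least 1.70. Scan gain differed between mid and late arrays in 3 of the 4 pairs of slide 2. It was equal on slide 1, where the lists still lay at least 1.61 apart in all 4 pairs, and in the other pair of slide 2 (1.77), so gain is unlikely to be the whole of it. After a G1 release, G1/S transcripts come before those of the CLB2 cluster. An exchange of every time label at once would put the CLB2 cluster below them, but it lay above by at least 1.61 in all 8 pairs. The time after release, which the design names, stays open as a hypothesis.

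Chance was weighed by splitting the samples otherwise, in a fit of 2 groups of 4. Of 35 splits, 2 called as many genes as the phase split or more (43 for the phase split, 3389 for the highest other), so chance was not excluded there. The highest was the split of the slides, which points to a structure of the samples by slide; with the slide as a block the phase split called 268. Splits that keep 2 samples of each slide on each side number 18, too few for a share under 0.05; with the block 1 of 18 reached the real 268, and the highest other was 0. For EdU the real count was 0, which any split reaches (35 of 35, and 18 of 18 with the block), so these splits say nothing about chance; the highest others were 3389, the slide split, and 268, the phase split.

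Across all genes, the EdU difference did not repeat between slides. On slide 1 the EdU differences of mid and late S correlated at r = 0.43 across genes, while between slides r reached at most 0.04. This is consistent with a difference between the EdU and control samples of slide 1 that both phases share. On slide 2 r was 0.02, which argues against a difference shared across all genes there. For single lists it stays open: on slide 2 the medians in mid and late S were 0.25 and 0.21 for cytosolic ribosomal proteins, 0.54 and 0.15 for glycolysis genes and 0.72 and 0.21 for core histones. The ribosomal proteins were also above 0 on slide 1 (0.16 and 0.10). In mid S of slide 2, 370 and 379 probes (Cy5 and Cy3) were saturated in cDNA without EdU, against 152 and 284 with it. In late S of slide 2 these were 78 and 490 without EdU, against 312 and 340 with it. Saturation was not tested as a source of these medians. On slide 1 the median cDNA signal was higher with EdU in both phases and dyes. With cDNA in Cy5 it was 1772.0 against 570.5 in mid S and 881.0 against 641.5 in late S. With cDNA in Cy3 it was 693.2 against 627.8 and 1349.2 against 1038.0. The genomic DNA reference of the same arrays was brighter with EdU as well. On arrays with cDNA in Cy5 its median was 1522.0 against 710.2 in mid S and 1098.2 against 788.5 in late S. On those with cDNA in Cy3 it was 1305.0 against 1232.8 and 1909.2 against 1184.0. That reference holds no RNA of the samples, so the brightness was not particular to the cDNA. Whether the difference of slide 1 came from EdU, from the cultures, from RNA handling or from this brightness stays open, as these were not tested apart. RNR3, at 1.37 on slide 1 and 0.29 on slide 2, is a gene to follow up.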
